A study of Mus musculus with 9 samples.

How the data were processed

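Poly(A)-selected RNA from 9 purified primary mouse cultures of 3 cell types, with 3 biological replicate experiments each, was sequenced as stranded mRNA libraries, per the labels' protocols. Astrocytes came from the cortex of pups at postnatal day 1 to 3 and were grown for about 21 days until confluent. Dorsal root ganglion (DRG) neurons, the sensory neurons beside the spinal cord, came from embryos at day 13.5 and were grown for about 2 weeks. Oligodendrocyte precursor cells (OPC), the dividing cells that give rise to myelinating oligodendrocytes, came from the cortex at postnatal day 6 to 9 and were grown for 6 to 7 days. Either sex was used. Donor age and time in culture therefore changed together with cell type in every comparison, and tissue of origin in those with DRG neurons. No comparison separates them from cell type. The labels give no sequencing date, lane or litter.

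Reads were aligned to the mouse build mm10 with TopHat2 and assigned with HTSeq, per the submitters' processing notes; their versions, the RefSeq release, the counting mode and the strand setting were not given in the sources used here. The deposited files hold raw read counts per RefSeq transcript accession, 1 file per library, with 33787 accessions and 5 totals of reads that were not assigned. No normalization had been applied. Counting per transcript sets aside every read shared by isoforms of 1 gene as ambiguous, so genes with more than 1 accession were under-counted and their counts cover isoform-specific reads only. Of all accessions, 33315 were named from the RefSeq table of GRCm38.p6, the assembly of mm10, and 193 from GENCODE vM21. Accessions without a name, 279 in number, were kept under their own identifier. Counts were added over the accessions of a gene, which gave 24170 genes, 19398 of them with 1 accession. Coordinates are those of the RefSeq table; transcript lengths came from GENCODE vM21. All named genes given with coordinates were annotated as protein coding.

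Assigned counts per library ran from 30710093 to 53594210, of 56683071 to 93305766 reads in all. Intervals of ratios are 95% counting intervals, and floors are 3 counts over the 3 libraries of a group; both cover counting error only, since the reads carry no molecular identifiers. Where a group had 0 counts, a fold is given as "at least", against that floor. With 1 to 3 counts in the lower group, the ratio is given with its counting interval. Levels are CPM as defined by edgeR, with library sizes scaled by TMM factors, as mean ± SD over n = 3 libraries unless stated.

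The test of each gene was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, on the summed counts of all 9 libraries in 1 model with 1 coefficient per cell type and 6 residual degrees of freedom. TMM factors and filterByExpr by cell type (minimum count 10) were used, which kept 14848 genes. Every p of a gene is adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05, and counts with at least a 2-fold difference are given beside. Each SE was calculated back as the size of the log2 fold change divided by the square root of the F statistic. It is not a standard error from the fit, and with few counts in a group it need not measure the uncertainty of the fold. Comparisons were DRG neurons against astrocytes, DRG neurons against OPC, OPC against astrocytes, and DRG neurons against the equally weighted mean of both glial types on the log scale. Genes enriched in a cell type passed the threshold with at least a 2-fold difference against each of the other two. Because such a pair of comparisons shares 3 libraries, the covariance and correlation of their log2 fold changes were also taken in 10 simulations in which no gene differed.

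Before the data were examined, the sample groups, tests, gene lists, named-gene rule and most alternatives were fixed. Gene lists covered linker histones; ISWI remodelers; CHD, INO80 and other Snf2-family ATPases; NuRD subunits; neuronal BAF and progenitor BAF subunits; histone variants; histone chaperones; replication-dependent core histones; DNA methylation enzymes; and repressive histone methylation enzymes with HP1 proteins. Cell type lists covered pan-neuronal, sensory neuron and central neuron markers; OPC; myelin and oligodendrocyte; astrocyte; reactive astrocyte; microglia; Schwann and satellite glia; fibroblast and mural; endothelial; ependymal; and muscle and epidermis genes. The remaining lists were cell cycle, synaptic vesicle, voltage-gated channel, cholesterol synthesis, glycolysis, central nervous system matrix, immediate early, interferon-induced, ribosomal protein and mitochondrially encoded genes. The last list had no member in the files, so 34 lists were tested. No gene stood in more than 1 list. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 102 tests, and again with a correlation estimated from the residuals. Counts of list members were also adjusted over the list alone.

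The named genes were, for each comparison of a pair of cell types, the 6 with the largest positive and the 6 with the largest negative log2 fold change. These had to pass the threshold, reach a mean of 20 CPM in the higher group, show no overlap of replicates and be no gene model. Added to these were all linker histones and the ATPases Smarca5, Smarca1, Chd1 to Chd5 and Ino80, up to 4 members of each list described with the smallest adjusted p, and the 8 enriched genes with the highest mean CPM per cell type. For cells that may have been carried over, the 3 list members with the highest mean CPM in the group concerned were given. Linker histone CPM were summed per library and compared by an exact two-sided permutation test, in which 3 against 3 libraries cannot give a p below 0.1. Some genes chosen by these rules, and 1 of the lists tested, are not reported here.

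Alternatives were DESeq2 1.42.0; limma-voom; RLE, upper-quartile and library-size scaling; no filter on low counts; a filter of 1 CPM in 3 libraries; models of only the libraries compared; replicate number as a block; thinning to the smallest library; and leaving out each library in turn. Added after the data had been seen were genes with 1 accession only, each accession on its own, removal of a length trend, and leaving out both Astrocytes replicate 1 and OPC replicate 3.

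The model was tested on simulated data with the counts and spread of these libraries. With 100 genes at 2-fold, 100 at 4-fold and the rest unchanged, edgeR recovered 4 and 53 of them between DRG neurons and astrocytes, with 4 false calls among 61. DESeq2 recovered 32 and 84, with 62 false calls among 178. With the real group means left in, edgeR recovered 52 of 100 genes at 2-fold and 90 of 100 at 4-fold, and called 45 of 2000 unchanged genes. A list with a simulated 2-fold difference in OPC was called in both comparisons with OPC at the preset correlation. Genes were drawn independently there, so this does not test lists whose genes vary together.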

Results

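The series measured mRNA in purified mouse cultures of astrocytes, DRG neurons and OPC, with 3 libraries of each. Assigned counts were 48556154, 38615051 and 33424457 in Astrocytes replicates 1 to 3, 30710093, 53594210 and 43963648 in DRG replicates 1 to 3, and 46197203, 47042387 and 40906260 in OPC replicates 1 to 3. Between 15889 genes (OPC replicate 1) and 17061 genes (DRG replicate 2) were detected. The 10 most abundant genes took 4.24 to 8.26% of the assigned counts. Correlations of log2 CPM across genes, which are not independent replicates, were 0.935 to 0.989 within astrocytes, 0.973 to 0.990 within DRG neurons and 0.967 to 0.983 within OPC. Between cell types they were 0.677 to 0.749 for astrocytes and DRG neurons, 0.761 to 0.850 for astrocytes and OPC, and 0.759 to 0.784 for DRG neurons and OPC. The first principal component held 54.3% of the variance and the second 35.1%.

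**Figure D1:**
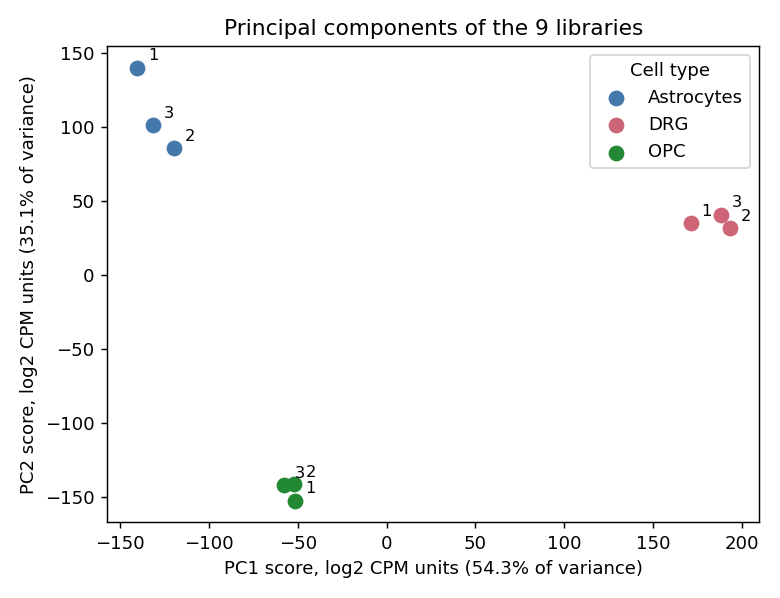
Scores of the 9 libraries on the first principal component (x axis, 54.3% of the variance) and the second (y axis, 35.1%), in log2 CPM units. Each point is a library with its replicate number, and colour gives the cell type; the 3 libraries of each cell type lie together.

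Marker genes followed the cell types. Pan-neuronal genes summed to 46000 ± 11300 CPM in DRG neurons, 1005 ± 78.8 in OPC and 536 ± 72.9 in astrocytes. Sensory neuron genes summed to 9073 ± 433 CPM in DRG neurons, 418 ± 132 in OPC and 933 ± 490 in astrocytes. OPC genes summed to 6465 ± 953 CPM in OPC, 1153 ± 569 in astrocytes and 14.4 ± 1.90 in DRG neurons. Astrocyte genes summed to 17700 ± 8520 CPM in astrocytes, 1708 ± 96.2 in DRG neurons and 1573 ± 108 in OPC.

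Markers of other cells differed between libraries of the same cell type. Astrocytes replicate 1 held 4267 CPM of microglia genes, against 811 and 760 in replicates 2 and 3. Its cell cycle genes summed to 674 CPM, against 3394 and 2614, and its fibroblast and mural genes to 1169 CPM, against 8458 and 9897. In OPC replicates 1 to 3 microglia genes summed to 94.5, 165 and 420 CPM. OPC replicate 3 had lower counts of long transcripts than replicates 1 and 2. Its median log2 ratio to them was 0.27 for genes with transcripts of 131 to 1814 nucleotides and −0.33 for those of 4355 nucleotides or more. At least 5 CPM on average was reached by 11 of 15 microglia genes in astrocytes, 6 in OPC and 2 in DRG neurons. Among the most abundant microglia genes of astrocytes were Csf1r (330 ± 351 CPM) and C1qa (254 ± 273). In OPC they included Tyrobp (28.7 ± 31.1) and C1qa (21.0 ± 23.1), and in DRG neurons C1qb (5.09 ± 1.11) and Aif1 (3.23 ± 1.62).

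**Figure D2:**
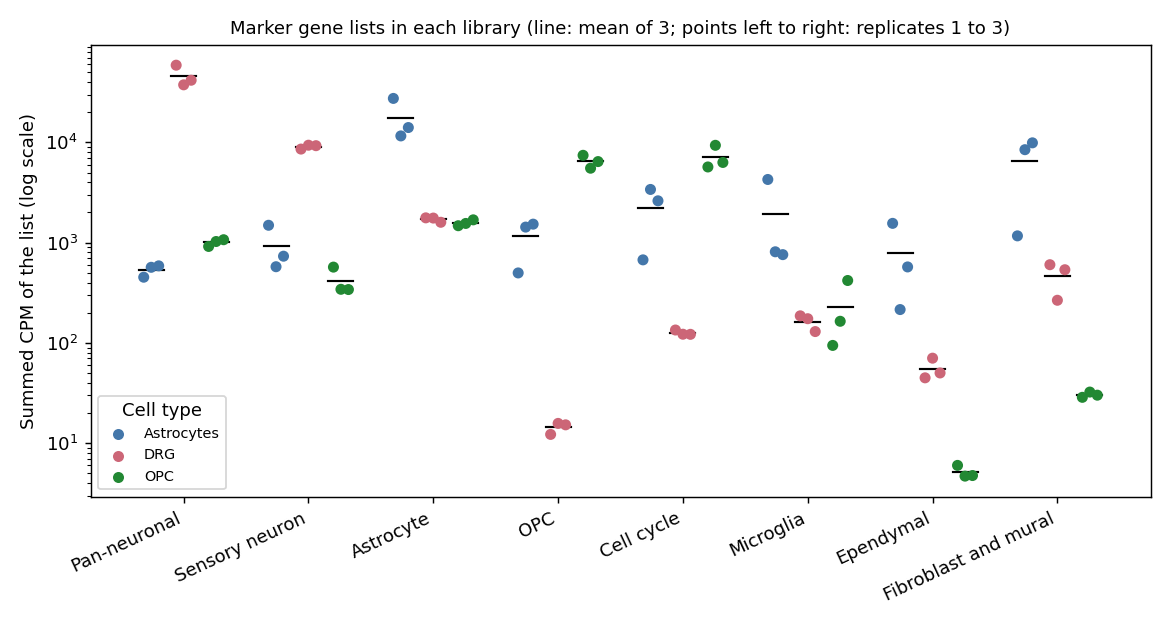
Summed CPM of 8 marker lists (y axis, log scale) in each of the 9 libraries; points are replicates 1 to 3 from left to right, lines are means of 3, and colours are cell types. Astrocytes replicate 1 held 4267 CPM of microglia genes and 674 CPM of cell cycle genes.

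**Figure D3:**
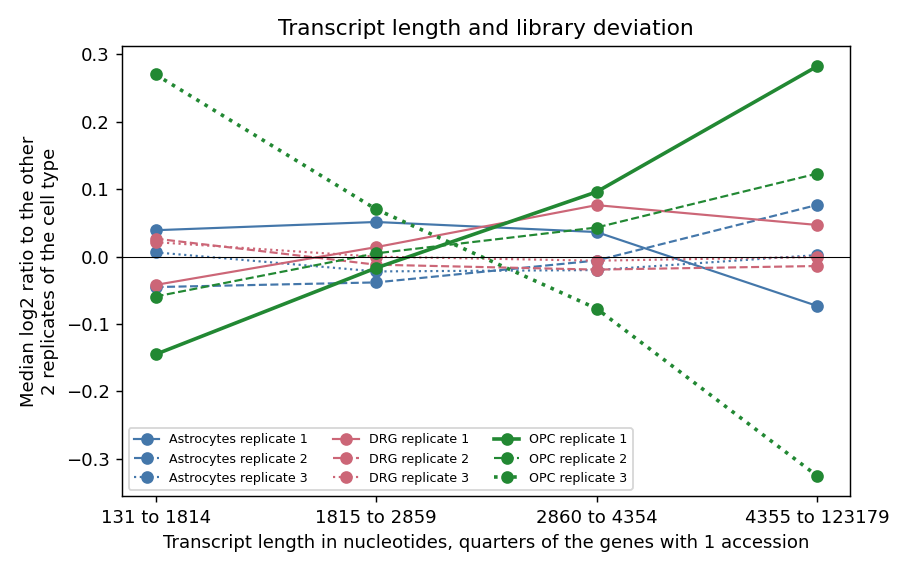
Median log2 ratio of each library to the other 2 replicates of its cell type (y axis) for the genes with 1 accession in 4 equal groups by transcript length in nucleotides (x axis); lines are the 9 libraries. OPC replicate 3 went from 0.27 in the group of the shortest transcripts to −0.33 in that of the longest.

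The series is about nucleosome spacing in neurons and glia, and the first question was how mRNA of linker histones, which bind the DNA between nucleosomes, differed between the cell types. H1f0, a replication-independent linker histone, was the most abundant in the poly(A) RNA of all 3, at 173 ± 8.17 CPM in astrocytes, 168 ± 28.7 in DRG neurons and 339 ± 73.4 in OPC. It was 2.01-fold lower in DRG neurons than in OPC (log2 −1.01, SE 0.20, adjusted p = 0.00229) and 1.95-fold higher in OPC than in astrocytes (log2 0.97, SE 0.20, adjusted p = 0.00382). Without Astrocytes replicate 1 and OPC replicate 3 the latter adjusted p was 0.0540. H1f2 went the other way, with 8.94 ± 2.64 CPM in OPC against 60.5 ± 30.5 in astrocytes (log2 −2.76, adjusted p = 0.000525) and 51.8 ± 6.48 in DRG neurons (DRG vs OPC, log2 2.53, adjusted p = 0.00052). Between DRG neurons and astrocytes neither H1f0 (log2 −0.04, adjusted p = 0.867) nor H1f2 (log2 −0.22, adjusted p = 0.625) passed the test.

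Summed linker histone mRNA in poly(A) RNA was 273 ± 53.6 CPM in astrocytes, 238 ± 38.1 in DRG neurons and 421 ± 104 in OPC. No pair of cell types passed the exact two-sided permutation test, whose smallest p for 3 against 3 libraries was 0.1. The ratio was 0.872 for DRG neurons to astrocytes (exact p = 0.5, adjusted 0.5), 0.566 for DRG neurons to OPC (exact p = 0.1, adjusted 0.3) and 1.54 for OPC to astrocytes (exact p = 0.2, adjusted 0.3). These sums rest on 8267 to 24572 reads per library. They were lowest in replicate 1 of both glial types, at 218 CPM in Astrocytes replicate 1 and 303 in OPC replicate 1, where 0 of the 7 linker histones tested were higher than in the other two replicates (median log2 ratios −0.99 and −0.45). H1f0 made up 64.8 ± 10.3% of them in astrocytes, 70.6 ± 1.24% in DRG neurons and 81.0 ± 3.37% in OPC, and H1f2 made up 21.2 ± 7.12%, 21.9 ± 1.85% and 2.19 ± 0.644%.

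H1f10 reached 32.3 ± 14 CPM in astrocytes, 15.5 ± 3.54 in DRG neurons and 72.6 ± 30.5 in OPC. It was lower in DRG neurons than in OPC (log2 −2.23, adjusted p = 0.00187) and higher in OPC than in astrocytes (log2 1.17, adjusted p = 0.0424), a call that 13 of 22 alternatives ended. Among these were leaving out Astrocytes replicate 1 (adjusted p = 0.0946), 2 (0.0517) or 3 (0.0561), DRG replicate 2 (0.0561) or 3 (0.0538), and OPC replicate 2 (0.124) or 3 (0.193). H1f10 in DRG neurons against astrocytes (log2 −1.06, adjusted p = 0.0531) passed without Astrocytes replicate 1 (0.0104) or OPC replicate 1 (0.0275). Transcripts of the clustered genes H1f1 to H1f5 largely lack poly(A) tails, so their levels here, H1f2 included, cover polyadenylated RNA only. H1f1, H1f3, H1f4 and H1f5 had mean levels from 0.0624 to 3.65 CPM. All 4 were lower in OPC than in astrocytes, with log2 fold changes from −4.16 (H1f4, adjusted p = 0.000483) to −2.78 (H1f3, adjusted p = 0.00968). The H1f1 change of −3.57 there was −4.94 without OPC replicate 2, and the H1f3 change was −2.07 without Astrocytes replicate 3 and −3.41 without OPC replicate 3. In DRG neurons, H1f4 and H1f3 were higher than in OPC (log2 2.63 and 2.50, adjusted p = 0.00333 and 0.0132). The H1f3 call ended without OPC replicate 2 (0.0547), and its log2 fold change was 3.23 without OPC replicate 3. H1f5 was lower in DRG neurons than in astrocytes (log2 −2.38, adjusted p = 0.00405). H1f5 against OPC had a log2 fold change of 1.42 (adjusted p = 0.0638, and 0.0495 without Astrocytes replicate 3). H1f4 and H1f1 also passed against astrocytes (adjusted p = 0.0282 and 0.0459). Adjusted over the linker histones alone, 1 of these 3 genes was lower in DRG neurons than in astrocytes, and 4 instead of 3 were higher than in OPC. The H1f4 call ended without Astrocytes replicate 3 (0.119) or DRG replicate 2 (0.0980). The H1f1 call ended without Astrocytes replicate 2 (0.0725) or 3 (0.154), DRG replicate 2 (0.158) or 3 (0.143), or OPC replicate 1 (0.0627), and its log2 fold change of −2.10 was −2.74 without DRG replicate 1. H1f3 against astrocytes (log2 −0.28, adjusted p = 0.724) and H1f1 against OPC (log2 1.47, adjusted p = 0.195) did not pass. H1f6, H1f7, H1f8 and Hils1 held at most 0.034% of linker histone CPM in any library. As lists, linker histones passed camera in no comparison (adjusted p = 0.503, 0.610 and 0.146 for DRG vs astrocytes, DRG vs OPC and OPC vs astrocytes).

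Of the remodelers, the ATPases that slide and space nucleosomes, 8 had been named in advance, Chd3 of the NuRD complex among them. Chd3 reached 650 ± 184 CPM in DRG neurons, 150 ± 34.5 in astrocytes and 20.1 ± 3.74 in OPC, so it was 4.35-fold higher in DRG neurons than in astrocytes (log2 2.12, adjusted p = 0.000169) and 32.3-fold higher than in OPC (log2 5.02, adjusted p = 4.41e-06). It was 7.44-fold lower in OPC than in astrocytes (log2 −2.90, adjusted p = 6.84e-05). The other NuRD ATPase, Chd4, was lower in DRG neurons (386 ± 17.5 CPM) than in OPC (631 ± 85.8; log2 −0.71, adjusted p = 0.00526), and astrocytes held 497 ± 51.2 CPM. Ino80 was lower in DRG neurons (29.6 ± 2.79 CPM) than in astrocytes (57.9 ± 8.59; log2 −0.97, adjusted p = 0.00372) and OPC (61.9 ± 14.7; log2 −1.06, adjusted p = 0.00225). Chd5, measured by isoform-specific reads of 2 accessions, was higher in DRG neurons (4.41 ± 1.83 CPM) than in astrocytes (0.857 ± 0.499; adjusted p = 0.00325) and OPC (1.32 ± 0.195; adjusted p = 0.0136).

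Smarca5, the ISWI ATPase that sets regular spacing, was 2.24-fold lower in DRG neurons (130 ± 8.83 CPM) than in OPC (291 ± 141; log2 −1.16, adjusted p = 0.0175). The call ended without DRG replicate 2 (0.0589), OPC replicate 1 (0.0576) or OPC replicate 2 (0.0682). Chd1, another spacing ATPase, was lower in DRG neurons (38.8 ± 5.91 CPM) than in OPC (93.4 ± 45.2; log2 −1.27, adjusted p = 0.0148), a call that ended without DRG replicate 2 (0.0523) or 3 (0.0506) or OPC replicate 2 (0.0608). OPC replicate 3 stood apart in both, with 128 CPM of Smarca5 against 360 and 383 in replicates 1 and 2, and 42.2 CPM of Chd1 against 110 and 128. Smarca5 in DRG neurons against astrocytes (206 ± 20 CPM; log2 −0.67, adjusted p = 0.125) passed without OPC replicate 3 (0.0071), and so did Smarca5 in OPC against astrocytes (log2 0.50, adjusted p = 0.260, and 0.00756 without it). Chd1 in DRG neurons against astrocytes (69.6 ± 14.6 CPM; adjusted p = 0.0722) passed without OPC replicate 3 (0.0124), and Chd2 in DRG neurons against OPC (74.5 ± 10 and 106 ± 39.2 CPM; adjusted p = 0.128) passed without it too (0.0279). Chd2 in DRG neurons against astrocytes (99.5 ± 7.89 CPM; adjusted p = 0.207), Chd4 in DRG neurons against astrocytes (0.0853), and Chd1, Chd2, Chd4, Chd5 and Ino80 in OPC against astrocytes did not pass (0.356, 0.792, 0.113, 0.321 and 0.730). With library size alone Chd2 (0.0434) and Chd4 (0.00902) passed in DRG neurons against astrocytes, as did Smarca5 (0.0446) and Chd1 (0.0302) there and Chd2 in DRG neurons against OPC (0.0493). With the length trend removed Chd4 passed in OPC against astrocytes (0.0375), Chd1 in DRG neurons against astrocytes (0.0481) and Chd2 in DRG neurons against OPC (0.0469). With only the compared libraries Smarca5 (0.00909) and Chd1 (0.0179) passed in DRG neurons against astrocytes. Smarca1, an ISWI ATPase with 2 accessions, had at most 0.362 CPM of isoform-specific reads in any library and was not tested.

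**Figure D4:**
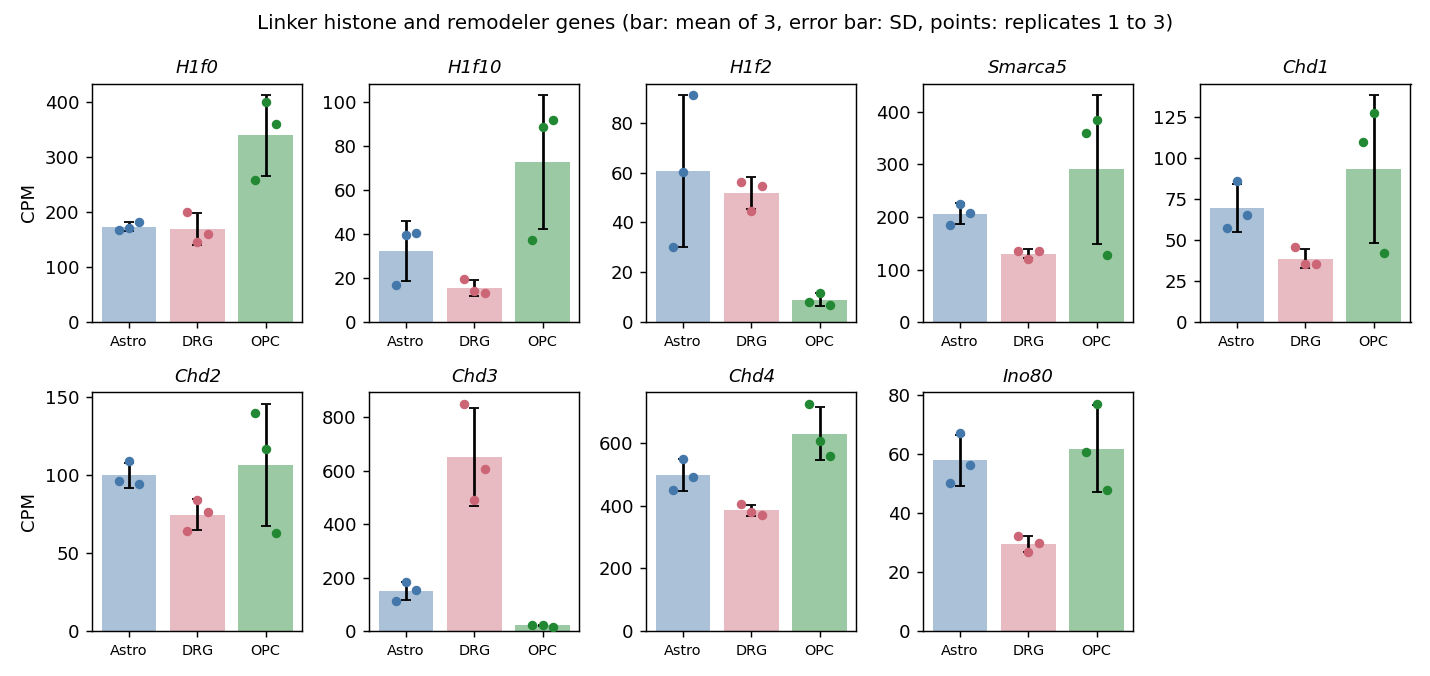
CPM (y axes, from 0) of 3 linker histone genes and 6 remodeler genes in astrocytes, DRG neurons and OPC; bars are means of 3 libraries, error bars SD, points replicates 1 to 3. Chd3 had 650 ± 184 CPM in DRG neurons, and OPC replicate 3 had 128 CPM of Smarca5.

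DRG neurons were compared with astrocytes to ask how neurons and this kind of glia differ in mRNA. In DRG neurons the synaptic release genes, voltage-gated channels and sensory neuron genes were higher, and in astrocytes the astrocyte markers, the cell cycle genes and the matrix genes were higher. With an estimated correlation only the synaptic and sensory lists passed (channel, astrocyte and matrix lists, adjusted p = 0.171; cell cycle, 0.565). Tubb3, the neuronal tubulin, reached 6320 ± 912 CPM in DRG neurons and 13.3 ± 4.76 in astrocytes, a 475-fold difference (log2 8.89, SE 0.45, adjusted p = 1.47e-06). Gfap, the intermediate filament of astrocytes, reached 2668 ± 281 CPM in astrocytes and 1.87 ± 0.899 in DRG neurons (log2 −10.49, SE 0.61, adjusted p = 2.48e-06), from isoform-specific reads of 2 accessions.

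Among the largest differences were homeobox genes of sensory neurons. Hoxd1 (chromosome 2, 74762980 to 74765142) reached 39.3 ± 19.0 CPM in DRG neurons with 0 counts in astrocytes, at least 1850-fold higher. Tlx3 reached 62.5 ± 17.6 CPM, a ratio of 8458 (95% counting interval 1518 to 334100), and Tlx2 66.6 ± 10.8 CPM, a ratio of 4465 (1236 to 36870). Slc17a6, the vesicular glutamate transporter VGLUT2, reached 751 ± 235 CPM (log2 11.67, SE 1.22, adjusted p = 5.03e-05). Nefm, a neurofilament subunit, reached 11410 ± 8633 CPM (log2 11.59, SE 1.69, adjusted p = 0.000365). Without Astrocytes replicate 2 the log2 fold changes were 13.90 for Slc17a6, 14.56 for Nefm, 14.38 for Tlx3 and 14.47 for Tlx2. Astrocytes then held 0 counts of Tlx3 and Tlx2, so the values of these genes give a direction and no measured size. Without Astrocytes replicate 1 those of Slc17a6 and Tlx2 were 11 and 11.19, and without DRG replicate 1 that of Nefm was 10.77. On the astrocyte side, Npvf (chromosome 6, 50650672 to 50654445) reached 53.9 ± 28.2 CPM with 0 counts in DRG neurons, at least 1937-fold. Traf1 reached 126 ± 173 CPM, a ratio of 17080 (3065 to 674700), with 326 CPM in Astrocytes replicate 1 and 20.4 and 32.7 in the other two. The neural precursor factors Sox21, Sox1 and Nr2e1 reached 75.3 ± 17.3, 80.7 ± 22.3 and 117 ± 23.0 CPM. Their ratios were 8820 (1583 to 348400) and 4745 (1313 to 39190) for Sox21 and Sox1, and the log2 fold change of Nr2e1 was −11.61 (adjusted p = 3.26e-07). Slco1a4, an organic anion transporter, reached 566 ± 440 CPM (log2 −11.86, adjusted p = 1.17e-05). Fitted log2 fold changes without single libraries were −11.16, −12.81 and −15.40 for Traf1 (Astrocytes replicate 1, DRG replicates 2 and 3), −14.62 for Sox21 (DRG replicate 2), and −11.02, −11.25 and −13.29 for Slco1a4 (Astrocytes replicate 1, DRG replicates 2 and 3). The Traf1 value without DRG replicate 3 and the Sox21 value rest on 0 counts in DRG neurons and likewise give no measured size.

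Neuronal groups were higher in DRG neurons. Of 18 synaptic vesicle genes tested, 18 were higher (camera adjusted p = 9.64e-16, and 0.038 with an estimated correlation), such as Bsn, an active zone protein (345 ± 64.4 against 3.36 ± 0.833 CPM), and Syngr3 (391 ± 7.76 against 9.23 ± 2.15 CPM). Of 20 sensory neuron genes, 18 were higher and 1 lower (adjusted p = 3.32e-11, and 0.038 with an estimated correlation). Among them were the sodium channel Scn11a (157 ± 12.5 against 0.201 ± 0.104 CPM), the ATP receptor P2rx3 (2023 ± 378 against 2.15 ± 1.26 CPM), the receptor Ret (122 ± 30.5 against 0.251 ± 0.118 CPM, 2 accessions) and Prrxl1 (46.9 ± 6.15 against 0.0409 ± 0.0380 CPM). The log2 fold change of Prrxl1 was 9.95, and 10.68 without Astrocytes replicate 1. Of 22 voltage-gated channel genes, 20 were higher and 1 lower, and 21 were higher when adjusted over the list alone (adjusted p = 2.72e-11, and adjusted p = 0.171 with an estimated correlation). Hcn2, Scn2b and Kcnh2 were 43.1-, 44.9- and 43.2-fold higher. Of 15 pan-neuronal genes, 13 were higher and 1 lower (adjusted p = 4.08e-09, and adjusted p = 0.171 with an estimated correlation), including Elavl3 (54.8-fold) and Syp, synaptophysin (80.3-fold). Of 16 glycolysis genes, 11 were higher (adjusted p = 0.00152, and adjusted p = 0.482 with an estimated correlation), with Eno2 52.1-fold, Gpi1 4.32-fold and Tpi1 3.58-fold higher.

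Glial and dividing-cell groups were lower in DRG neurons. Of 16 astrocyte genes tested, 14 were lower and 1 higher (adjusted p = 5.35e-09, and adjusted p = 0.171 with an estimated correlation), such as the glutamate transporter Slc1a3 (2.36 ± 1.41 against 1411 ± 144 CPM) and Acsbg1 (2.84 ± 1.34 against 547 ± 108 CPM). Sox9 held 0.770 ± 0.593 against 253 ± 115 CPM (log2 −8.41, and −9.19 without DRG replicate 1). Of 15 central nervous system matrix genes, 12 were lower and 1 higher (adjusted p = 5.58e-05, and adjusted p = 0.171 with an estimated correlation), with Gpc4 46.2-fold and Ptprz1 88.7-fold lower. Of 14 OPC genes, 10 were lower and 1 higher (adjusted p = 0.000156, and adjusted p = 0.319 with an estimated correlation), among them C1ql1 (0.107 ± 0.0586 against 67.1 ± 30.3 CPM). All but 1 of 23 cell cycle genes, 22, were lower (adjusted p = 9.02e-07, and adjusted p = 0.565 with an estimated correlation), including the replication helicase subunits Mcm3 (44.8-fold), Mcm7 (13.0-fold) and Mcm4 (6.23-fold) and the kinase Cdk1 (79.3-fold). These genes stood at 674 CPM in Astrocytes replicate 1 against 3394 and 2614 in the other two.

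Histone variant genes and markers of other cells were also lower in DRG neurons. Of 9 histone variant genes, 7 were lower, 8 when adjusted over the list alone (adjusted p = 0.00439, and adjusted p = 0.427 with an estimated correlation), with H2az2 14.2-fold, H3f3a 8.46-fold and H3f3b 2.59-fold lower. The HMG genes Hmgb2, Hmgn2 and Hmgn1 were 30.6-, 12.2- and 11-fold lower. All 14 microglia genes tested were lower (adjusted p = 0.00557, and adjusted p = 0.691 with an estimated correlation), as were the 7 ependymal genes (adjusted p = 0.0441, and adjusted p = 0.691 with an estimated correlation), a call that ended without DRG replicate 1 (0.0711). Astrocytes replicate 1 held more of both than the other two, with 500 CPM of Cx3cr1 against 74.9 and 80.1, 734 CPM of Csf1r against 136 and 118, and 998 CPM of Foxj1, a regulator of cilia, against 168 and 459. Without it the log2 fold changes went from −10.32 to −8.83 for Cx3cr1, from −8.56 to −7.19 for Csf1r, from −3.61 to −2.83 for Foxj1 and from −3.34 to −2.24 for Rsph1, and that of Csf1r was −9.37 without DRG replicate 1. Histone chaperone (adjusted p = 0.827), ISWI (0.197), NuRD (0.215), repressive histone methylation (0.178), CHD and INO80 (0.414), neuronal BAF (0.569) and progenitor BAF genes (0.794) did not pass. Interferon-induced genes did not pass either (0.0601, and 0.0291 with replicate number as a block), nor did cholesterol synthesis (0.136, and 0.0379 with the block), reactive astrocyte (0.0988), Schwann and satellite glia (0.824), endothelial (0.794), muscle and epidermis (0.983), DNA methylation (0.973) or immediate early genes (0.814). Of the Schwann and satellite glia genes, Pmp22 and Cdh19 stood at 233 ± 74.2 and 6.15 ± 3.73 CPM in DRG neurons. Central neuron genes (0.791) did not pass, although Slc17a7, the glutamate transporter VGLUT1, held 262 ± 50.1 CPM in DRG neurons.

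Between DRG neurons and astrocytes, 8938 of 14848 genes passed the edgeR test, 4075 higher and 4863 lower in DRG neurons, and 7464 of them differed at least 2-fold. With library size alone 3376 were higher and 5736 lower. Replicates did not overlap for 10244 genes, or 69.0%, where chance gives 10%. With Astrocytes replicate 1 and OPC replicate 3 left out, 9303 genes passed. Of 34 lists 13 passed; list counts adjusted over the list alone equalled those given except where stated.

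DRG neurons were then compared with OPC, the other kind of glia. Sensory and synaptic genes were again higher in the neurons, while ribosomal protein, cell cycle and histone variant genes were higher in OPC. With an estimated correlation no list passed (adjusted p = 0.171 or more). Olig2, the transcription factor of the oligodendrocyte lineage, reached 1327 ± 120 CPM in OPC and 0.275 ± 0.243 in DRG neurons (log2 −12.12, SE 0.95, adjusted p = 1.29e-05). Uchl1, a neuronal ubiquitin hydrolase, reached 3409 ± 730 CPM in DRG neurons and 206 ± 26 in OPC (log2 4.05, SE 0.24, adjusted p = 3.63e-06).

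Genes with 0 counts in OPC headed the neuronal side. These were Ppp1r1c (50.7 ± 8.89 CPM, at least 2228-fold, chromosome 2, 79707780 to 79818546), the homeobox genes Hoxb7 (44.5 ± 8.31 CPM, at least 1979-fold) and Hoxc10 (25.3 ± 7.25 CPM, at least 1113-fold), and the sensory neuropeptide gene Calcb (21.4 ± 3.62 CPM, at least 981-fold). The values of Ppp1r1c, its 0 counts in OPC included, cover isoform-specific reads only. Tlx2 had a ratio of 9200 (1651 to 363400) and Epn3, at 60.5 ± 9.35 CPM, a ratio of 8156 (1463 to 322200). On the OPC side, Neu4 reached 24.7 ± 35.1 CPM with 0 counts in DRG neurons, at least 942-fold, with 65.1 CPM in OPC replicate 1 against 2.79 and 6.16 in the other two. Gsx1 reached 94.8 ± 32.4 CPM, a ratio of 11000 (1974 to 434400). Sox21 had a ratio of 4906 (880 to 193800). Bcas1, counted by isoform-specific reads of 2 accessions, reached 40.7 ± 24.3 CPM, a ratio of 4694 (842 to 185500). Without single libraries the fitted log2 fold changes were 14.44 for Tlx2 and 14.30 for Epn3 (OPC replicate 2), −10.57 for Neu4 (OPC replicate 1), and −14.96 for Gsx1 and −13.79 for Sox21 (DRG replicate 2). For Bcas1 they were −11.18, −13.78 and −11.17 (DRG replicates 2 and 3, OPC replicate 1). Apart from Bcas1 without DRG replicate 2 or OPC replicate 1, the lower group then held 0 counts. Those values give a direction and no measured size.

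Of 18 synaptic vesicle genes, 18 were higher in DRG neurons (adjusted p = 1.59e-09, and adjusted p = 0.171 with an estimated correlation), such as Vamp2, the vesicle SNARE (6.31-fold), and Syngr3 (14.6-fold). Of 20 sensory neuron genes, 18 were higher and 2 lower (adjusted p = 1.34e-10, and adjusted p = 0.171 with an estimated correlation), including Scn11a (157 ± 12.5 against 0.0809 ± 0.0315 CPM). Pan-neuronal genes were higher in 12 of 15 cases and lower in 2 (adjusted p = 0.000145, and adjusted p = 0.301 with an estimated correlation), with Tubb3 67.0-fold and Syp 28.8-fold higher. Voltage-gated channel genes were higher in 17 of 22 cases and lower in 2 (adjusted p = 3.48e-05, and adjusted p = 0.301 with an estimated correlation), with Kcnd1 253-fold and Scn2b 16.2-fold higher. Of 16 glycolysis genes, 13 were higher (adjusted p = 1.74e-05, and adjusted p = 0.343 with an estimated correlation), with Eno2 184-fold, Tpi1 5.23-fold and Gpi1 5.60-fold higher. Fibroblast and mural genes were higher in 12 of 13 cases and lower in 1 (adjusted p = 0.00194, and adjusted p = 0.634 with an estimated correlation). Their most abundant members in DRG neurons were Col3a1 (134 ± 48.2 CPM), Col1a2 (119 ± 40.2 CPM) and Col1a1 (89.0 ± 16.6 CPM); Col1a2 had a log2 fold change of 8.59, and 9.21 without OPC replicate 3. Genes of reactive astrocytes were higher in 8 of 11 cases and lower in 1 (adjusted p = 0.00444, and adjusted p = 0.171 with an estimated correlation). Members that were higher act outside astrocytes too, such as Hspb1, a small heat shock protein (179 ± 32.9 against 0.109 ± 0.0491 CPM), and S1pr3, a sphingosine phosphate receptor (572 ± 365 against 0.529 ± 0.429 CPM). The log2 fold change of S1pr3 was 10.05, and 10.91 without OPC replicate 2.

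Ribosomal protein genes were lower in DRG neurons than in OPC for 69 of 77 genes and higher for 2, with 71 lower when adjusted over the list alone (adjusted p = 5.29e-20, and adjusted p = 0.342 with an estimated correlation). Their sum was 18320 ± 779 CPM in DRG neurons and 67990 ± 10700 in OPC, and Rps3a1 and Rps16 were 5.13- and 5.99-fold lower. All 23 cell cycle genes were lower (adjusted p = 4.22e-12, and adjusted p = 0.360 with an estimated correlation), with Mcm3 145-fold, Mcm7 44.2-fold and Pcna, the replication clamp, 13.8-fold lower. Of 14 OPC genes, 13 were lower and 1 higher (adjusted p = 3.6e-09, and adjusted p = 0.171 with an estimated correlation), including Xylt1 (0.550 ± 0.0432 against 230 ± 23.2 CPM).

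Several chromatin lists set these cell types apart as well. All 9 histone variant genes were lower in DRG neurons (adjusted p = 1.72e-07, and adjusted p = 0.237 with an estimated correlation), such as H2az2 (24.3-fold), H3f3a (17.2-fold), Macroh2a2 (8.45-fold) and H3f3b (7.10-fold). The HMG genes Hmgb2, Hmgn2, Hmgn1 and Hmgb1 were 207-, 60.7-, 29.3- and 7.41-fold lower. Of 13 ISWI genes, 9 were lower, 10 when adjusted over the list alone (adjusted p = 0.0072, and adjusted p = 0.378 with an estimated correlation), among them Rbbp4 (4.09-fold) and Baz1b (3.88-fold). Histone chaperone genes were lower in 13 of 18 cases and higher in 3, with 14 lower when adjusted over the list alone (adjusted p = 0.00895, and adjusted p = 0.442 with an estimated correlation). Hira, the chaperone of the histone variant H3.3, was 3.83-fold and Chaf1a 15.2-fold lower, while Nap1l2 was 9.61-fold higher. This list did not pass among genes with 1 accession (0.228) or with the length trend removed (0.202). Repressive histone methylation genes were lower in 9 of 11 cases and higher in 1 (adjusted p = 0.00612, and adjusted p = 0.398 with an estimated correlation), with Trim28 4.63-fold and Cbx3 5.96-fold lower; the list did not pass among genes with 1 accession (0.0682) or with the length trend removed (0.0810). NuRD subunit genes were lower in 7 of 9 cases and higher in 1 (adjusted p = 0.0244, and adjusted p = 0.319 with an estimated correlation), with Mta2 5.06-fold, Hdac1 3.99-fold and Mbd3 3.95-fold lower. Progenitor BAF genes were lower in 4 of 5 cases and higher in 1 (adjusted p = 0.0338, and adjusted p = 0.301 with an estimated correlation), with Actl6a 7.76-fold and Smarcd1 4.06-fold lower. Without Astrocytes replicate 1 and OPC replicate 3 the NuRD and progenitor BAF lists did not pass (0.0523 and 0.0676). CHD and INO80 genes (0.159), DNA methylation genes (0.408), central neuron genes (0.997) and myelin genes (0.302) did not pass either. Nor did neuronal BAF genes (0.483), of which 3 of 5 were lower and 1 higher in DRG neurons than in OPC.

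Between DRG neurons and OPC, 8833 genes passed, 4217 higher and 4616 lower in DRG neurons, and 7399 differed at least 2-fold. Which side held more genes depended on the scaling: RLE gave 4712 higher and 4046 lower, upper quartiles 4621 and 4120, and library size 3880 and 5108. Without OPC replicate 3, 55.8% of the genes that passed were higher in DRG neurons. Replicates did not overlap for 10014 genes, or 67.4%, where chance gives 10%. With Astrocytes replicate 1 and OPC replicate 3 left out, 9169 genes passed. Of 34 lists 17 passed; list counts adjusted over the list alone equalled those given except where stated.

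OPC were compared with astrocytes to ask how the glial types differ. Ribosomal protein, cell cycle, histone variant and OPC genes were higher in OPC, while astrocyte, reactive astrocyte and fibroblast and mural genes were higher in astrocytes. With an estimated correlation only the reactive astrocyte list passed; the other 6 had an adjusted p of 0.171 or more. Cspg4, the NG2 proteoglycan of OPC, reached 1088 ± 276 CPM in OPC and 23.6 ± 12.9 in astrocytes (log2 5.53, SE 0.58, adjusted p = 0.000101). Clu, clusterin, reached 2107 ± 1151 CPM in astrocytes and 4.47 ± 0.661 in OPC (log2 −8.88, SE 0.48, adjusted p = 4.96e-06).

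Asic4 (chromosome 1, 75450510 to 75474340) reached 63.8 ± 11.9 CPM in OPC, a ratio of 2778 (950 to 13470) to astrocytes, and Neu4 had a ratio of 1070 (366 to 5189). Gpr17, a receptor of OPC on the way to differentiation, had 786 CPM in OPC replicate 1 against 9.44 and 9.84 in replicates 2 and 3 (log2 9.34, adjusted p = 0.00374). Its log2 fold change was 4.56 without OPC replicate 1 and 9.93 without Astrocytes replicate 1, and it did not pass with limma-voom (0.0669). Dll3, a Notch pathway ligand, reached 221 ± 41.1 CPM (log2 9.06, adjusted p = 1.99e-05) and Rph3a 45.1 ± 30.3 CPM (log2 8.58, adjusted p = 1.75e-05, and 7.89 without OPC replicate 1). Sox10, which drives the oligodendrocyte lineage, reached 516 ± 201 CPM (log2 8.48, adjusted p = 6.5e-05, and 9.29 without Astrocytes replicate 3). On the astrocyte side, Akr1c14 (193 ± 63.0 CPM) had 0 counts in OPC and was at least 8698-fold higher. The small proteoglycan genes Ogn and Fmod reached 229 ± 61.3 CPM, a ratio of 31730 (5694 to 1253000), and 507 ± 32.9 CPM (log2 −13.63, adjusted p = 4.61e-06). Slco1a4 had a log2 fold change of −13.55 (adjusted p = 2.27e-05), and −12.69 without Astrocytes replicate 1, and Col8a1, at 467 ± 257 CPM, one of −13.52 (adjusted p = 2.71e-05). Without OPC replicate 2 the log2 fold changes of Ogn and Col8a1 were −16.21 and −14.11. OPC then held 0 counts of Ogn, so its value gives a direction and no measured size. Without single libraries that of Asic4 was 10.59 (Astrocytes replicate 1) and 12.12 (Astrocytes replicate 2), and that of Neu4 (9.87 with all libraries) was 9.22 and 10.83 (Astrocytes replicates 1 and 3) and 7.40 (OPC replicate 1).

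Ribosomal protein genes were higher in OPC for 72 of 77 genes and lower for 1 (adjusted p = 2.49e-23, and adjusted p = 0.301 with an estimated correlation), with Rpl37 3.66-fold and Rpl7a 3.69-fold higher. The sums were 67990 ± 10700 CPM in OPC and 22140 ± 1730 in astrocytes. Of 14 OPC genes, 11 were higher, 12 when adjusted over the list alone (adjusted p = 0.000321, and adjusted p = 0.319 with an estimated correlation). Astrocyte libraries held Olig1, a lineage factor of this list, at 223, 977 and 1004 CPM in replicates 1 to 3. Cell cycle genes were higher in OPC for 14 of 23 genes, 15 when adjusted over the list alone (adjusted p = 0.000922, and adjusted p = 0.686 with an estimated correlation), with Mcm2 4.52-fold, Mcm6 3.56-fold, Mcm7 3.40-fold and Pcna 2.92-fold higher; Astrocytes replicate 1 had 674 CPM of the list. Histone variant genes were higher in 7 of 9 cases (adjusted p = 0.00297, and adjusted p = 0.412 with an estimated correlation), with Macroh2a2 9.12-fold, H2az1 4.69-fold, H3f3b 2.74-fold and H2az2 1.71-fold higher; H2az2 did not pass without Astrocytes replicate 1 and OPC replicate 3 together (0.0550). The HMG genes Hmgb3, Hmgb2, Hmgn2 and Hmgb1 were 6.79-, 6.78-, 4.97- and 2.86-fold higher. Histone chaperone genes were higher in 11 of 18 cases (adjusted p = 0.000911, and adjusted p = 0.343 with an estimated correlation), with Nap1l2 6.33-fold, Hira 2.96-fold and Nap1l5 12.9-fold higher; the log2 fold change of Nap1l5 was 3.69, and 4.63 without Astrocytes replicate 1. The 5 progenitor BAF genes tested were higher (adjusted p = 0.00195, and adjusted p = 0.171 with an estimated correlation), with Smarcd1 6.38-fold and Actl6a 2.38-fold higher. Of 5 neuronal BAF genes, 4 were higher (adjusted p = 0.0225, and adjusted p = 0.237 with an estimated correlation), with Actl6b 13.1-fold and Dpf1 3.93-fold higher.

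Genes of neuronal lists were higher in OPC than in astrocytes. Synaptic vesicle genes were higher in 14 of 18 cases (adjusted p = 8.32e-05, and adjusted p = 0.231 with an estimated correlation), such as Bsn (16.3-fold), Unc13a (7.57-fold) and Syngr3 (2.90-fold). Cplx1 held 66.1 ± 9.94 against 0.731 ± 0.855 CPM (log2 6.51, and 5.92 and 8.15 without Astrocytes replicates 1 and 2). Voltage-gated channel genes were higher in 14 of 22 cases and lower in 1 (adjusted p = 7.48e-05, and adjusted p = 0.301 with an estimated correlation), including Hcn2 (5.34-fold) and Kcnh2 (6.50-fold). Pan-neuronal genes were higher in 9 of 15 cases and lower in 2 (adjusted p = 0.000879, and adjusted p = 0.319 with an estimated correlation), with Elavl3 at 122 ± 25.7, Tubb3 at 94.3 ± 30.3 and Ina at 44.3 ± 3.79 CPM in OPC. Sensory neuron genes (0.777) and central neuron genes (0.758) did not pass; the most abundant central neuron gene of OPC was Gad1, at 47.7 ± 16.0 CPM.

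Astrocyte genes were lower in OPC for 12 of 16 genes, 14 when adjusted over the list alone (adjusted p = 6.12e-10, and adjusted p = 0.171 with an estimated correlation). Gfap held 0.418 ± 0.223 against 2668 ± 281 CPM (log2 −12.65, and −13.26 without OPC replicate 3), the gap junction gene Gja1 1.45 ± 0.650 against 709 ± 167 CPM, and Id3 20 ± 8.51 against 490 ± 75.5 CPM. All 11 reactive astrocyte genes tested were lower (adjusted p = 1.82e-08, and 0.038 with an estimated correlation). Osmr, the oncostatin M receptor, held 0.0872 ± 0.0342 against 155 ± 20.3 CPM, and S1pr3 0.529 ± 0.429 against 223 ± 5.61 CPM (log2 −8.70, and −9.55 without OPC replicate 2). Central nervous system matrix genes were lower in 8 of 15 cases and higher in 2, 3 when adjusted over the list alone (adjusted p = 0.00345, and adjusted p = 0.360 with an estimated correlation). Gpc4 was 91.3-fold and Lamb2, a laminin subunit, 398-fold lower, and Thbs1, thrombospondin, had a log2 fold change of −9.74 (−10.55 without OPC replicate 3). Replication-dependent core histone genes were lower in 13 of 19 cases and higher in 1, with 14 lower when adjusted over the list alone (adjusted p = 0.00278, and adjusted p = 0.412 with an estimated correlation). Poly(A) selection leaves most of their transcripts out, and their sum was 48.2 ± 13.4 CPM in OPC and 145 ± 20.4 in astrocytes; H4c9, H4c8 and H2bc4 were 17.4-, 29.7- and 13.8-fold lower. This list did not pass between DRG neurons and astrocytes (0.653) or OPC (0.0657, and 0.0135 with replicate number as a block).

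Markers of other cells were lower in OPC than in astrocytes. Fibroblast and mural genes were lower in 11 of 13 cases and higher in 1 (adjusted p = 0.000493, and adjusted p = 0.566 with an estimated correlation). The contractile genes Acta2 and Tagln reached 3683 ± 2913 and 2509 ± 1547 CPM in astrocytes, and Acta2 stood at 413 CPM in replicate 1 against 4639 and 5998. Acta2 had a log2 fold change of −12.59, and −13.28 without OPC replicate 3. The 7 ependymal genes tested were lower (adjusted p = 0.000551, and adjusted p = 0.421 with an estimated correlation), with Foxj1, Rsph1 and Rarres2 at 542 ± 421, 88.5 ± 83.5 and 40.4 ± 48.0 CPM in astrocytes. Without Astrocytes replicate 1 the log2 fold changes of Foxj1 and Rsph1 went from −7.09 to −6.30 and from −7.44 to −6.34. Interferon-induced genes were lower in 9 of 12 cases (adjusted p = 6.61e-05, and adjusted p = 0.412 with an estimated correlation); Ifitm3 had 285, 113 and 132 CPM and Ifit3 129, 38.0 and 27 CPM in Astrocytes replicates 1 to 3. The log2 fold change of Ifit3 was −7.23, and −6.23 without replicate 1. Microglia genes were lower in 11 of 14 cases, 12 when adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.705 with an estimated correlation). Cx3cr1 went from −5.73 to −4.24 and Csf1r from −5.14 to −3.76 on the log2 scale without Astrocytes replicate 1, and to −7.26 and −6.12 without OPC replicate 3. Myelin genes did not pass (0.123); Ugt8a and Mbp, the latter counted over 8 accessions, stood at 83.3 ± 48.0 and 36.6 ± 3.46 CPM in OPC. Glycolysis (0.143), ISWI (0.151), NuRD (0.328), CHD and INO80 (0.635), repressive methylation (0.134) and cholesterol synthesis genes (0.0589, and 0.00418 with replicate number as a block) did not pass either. In 10 of the 102 list tests the median, mean and test of the list differed in sign, and each of these lists failed the test. They were DNA methylation, endothelial, fibroblast and mural, myelin, progenitor BAF, and muscle and epidermis genes between DRG neurons and astrocytes, cholesterol and Schwann genes between DRG neurons and OPC, and central and sensory neuron genes between OPC and astrocytes.

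Between OPC and astrocytes, 7689 genes passed, 3903 higher and 3786 lower in OPC, and 6092 differed at least 2-fold. The other scalings turned this balance, with 3431 higher and 4017 lower for RLE, 3314 and 4073 for upper quartiles, and 3425 and 4041 for library size. Replicates did not overlap for 9098 genes, or 61.3%, where chance gives 10%. With Astrocytes replicate 1 and OPC replicate 3 left out, 6523 genes passed. Of 34 lists 19 passed; list counts adjusted over the list alone equalled those given except where stated.

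DRG neurons were last compared with the mean of both glial types, since the series sets neurons against glia. Genes higher in DRG neurons than in each glial type were led by neurofilaments and the neuronal cytoskeleton. Nefm reached 11410 ± 8633 CPM, Nefl 10510 ± 4498, Nefh 5616 ± 1686, Map1b, a microtubule protein, 10340 ± 2529 and Tubb3 6320 ± 912 CPM. Ngfr, the low-affinity neurotrophin receptor, reached 5866 ± 2640 CPM, and Ywhag 5159 ± 1089 CPM. In all, 2198 genes were enriched in DRG neurons. Against the mean of both glial types 9093 genes passed, 4326 higher and 4767 lower, and 7149 differed at least 2-fold. RLE gave 4706 higher and 4338 lower, upper quartiles 4575 and 4448, and library size 3738 and 5562. Fitted log2 fold changes against astrocytes without Astrocytes replicate 2 were 14.91 for Nefl, 13.34 for Nefh and 10.69 for Ngfr, against 11.46, 10.61 and 8.67 with all libraries. Those of Nefl and Nefh were 10.86 and 10.01 without Astrocytes replicate 1. Against OPC, Ngfr and Nefh had 10.27 and 11.06, and 11.13 and 12.11 without OPC replicate 2, and Nefm 9.29, and 8.47 without DRG replicate 1.

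Genes enriched in OPC numbered 1301. Among the most abundant of them were the elongation factor gene Eef1a1 at 14210 ± 3147 CPM (2.44-fold over astrocytes, 3.74-fold over DRG neurons), Rpsa at 3240 ± 596, Rplp0 at 2741 ± 510 and Rps2 at 2248 ± 512 CPM. Cfl1, an actin-severing protein, reached 3413 ± 731, Tpt1 3291 ± 843, the ferritin gene Ftl1 3468 ± 1171 and the cell cycle gene Ccnd1 2495 ± 879 CPM. Against astrocytes, Ftl1 (adjusted p = 0.0225) did not pass without OPC replicate 3 (0.152) or Astrocytes replicate 2 (0.0693) or 3 (0.0812). Rps2 (adjusted p = 0.0116) did not pass without OPC replicate 3 (0.0784), and without both that library and Astrocytes replicate 1 neither Rps2 (0.129) nor Ccnd1 (0.0712) passed.

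Genes enriched in astrocytes numbered 2049. The most abundant were Pea15a (10100 ± 2296 CPM), Igfbp5 (7733 ± 1263), the intermediate filament gene Vim (6536 ± 1280), the lipoprotein gene Apoe (6304 ± 6293), Igfbp2 (4216 ± 2941), Acta2, the potassium channel gene Kcnj10 (3226 ± 652) and Cpe (3066 ± 1563). Apoe stood at 13550 CPM in replicate 1 against 2242 and 3117, and Igfbp2 at 866 against 6371 and 5411. Without Astrocytes replicate 1 the log2 fold change of Apoe went from −6.01 to −4.78 against DRG neurons and from −5.40 to −4.17 against OPC. Without DRG replicate 1 the log2 fold changes of Apoe, Igfbp2 (−7.15) and Acta2 (−6.49) were −6.74, −7.82 and −7.33. Against OPC, that of Apoe was −6.13 without OPC replicate 3 and that of Kcnj10 (−4.64) −5.38 without OPC replicate 1. Cpe in DRG neurons (adjusted p = 0.0208) did not pass without Astrocytes replicate 1 (0.0584), DRG replicate 2 (0.0510) or DRG replicate 3 (0.0740).

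For independent lists of the same sizes, 818.4, 669.7 and 958.2 genes enriched in DRG neurons, OPC and astrocytes would be found. The covariances of the paired log2 fold changes were 5.17, 2.55 and 3.78, against 0.132, 0.128 and 0.128 in 10 simulations without differing genes. Their correlations were 0.622, 0.365 and 0.502, against 0.507, 0.496 and 0.496. Comparisons that share a group correlate near the simulated values when all groups vary alike, with or without differing genes. The correlations therefore cannot tell shared libraries from real differences. Part of the excess over independent lists may come from the libraries that each pair of comparisons shares, and groups of 3 cannot be split to remove it. When Astrocytes replicate 1 and OPC replicate 3 were left out, the enriched genes numbered 2642, 918 and 1888 for DRG neurons, OPC and astrocytes, and 9617 genes passed between DRG neurons and the mean of both glial types.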

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

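Chosen after the result was seen were the tests of a microglia share, of dilution and of length-matched genes for Astrocytes replicate 1, all tests for OPC replicate 3, and the counts over genes with 1 accession.

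Reads set aside as ambiguous between features, which no comparison uses, made up 22.0 to 24.7% of all reads in the 9 libraries. They are given because the data hold such reads, and no control sets a level for them. Their share was 22.2 ± 0.207% in astrocytes, 23.9 ± 1.25% in DRG neurons and 22.6 ± 0.410% in OPC (n = 3 each). Among 11603 tested genes with 1 accession, 7130 passed between DRG neurons and astrocytes, 7094 between DRG neurons and OPC, and 6359 between OPC and astrocytes.

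Astrocytes replicate 1 differed from replicates 2 and 3 in more microglia, ependymal (7 of 7 higher) and interferon-induced genes (12 of 12) and fewer cell cycle (0 of 23 higher), cholesterol synthesis (0 of 20, median log2 ratio −1.39), linker histone (0 of 7, median −0.99) and fibroblast and mural genes (0 of 13). The tables argue against dilution of astrocytes as the reason for the low cell cycle genes, because their median log2 ratio lay −3.16 away from that of the astrocyte list, which was itself up by 0.44. They also argue against loss of long transcripts as the reason, because genes matched on length and level lay 2.63 above the cell cycle list on the log2 scale. A larger share of microglia in that culture may account for the microglia genes, with a median log2 ratio of 2.58 and 14 of 14 genes higher, but these genes had been seen to differ before the test. Its length trend was −0.11 per doubling of transcript length, against 0.04 in DRG replicate 1, 0.18 in OPC replicate 1 and −0.27 in OPC replicate 3. Slopes within a cell type mirror each other, as each is taken against the other replicates, so these set no independent level. Length-dependent loss over that library as a whole therefore stays open. A culture with fewer dividing cells, of whatever type, was not tested and stays open too. The astrocyte list gauges astrocytes only, and fibroblast and mural genes had a median log2 ratio of −2.54.

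OPC replicate 3 had fewer reads of 13 of 17 CHD and INO80 genes, and of Mki67 and Top2a among the cell cycle genes, and 4 of 13 ISWI genes were higher. Some other chromatin lists went the same way, with 4 of 11 repressive histone methylation (median log2 ratio −0.34), 7 of 18 histone chaperone (−0.15) and 2 of 5 DNA methylation genes (−0.03) higher. Others went the other way in it, with 9 of 9 histone variant (median log2 ratio 0.41), 7 of 9 NuRD, 5 of 5 progenitor BAF, 15 of 19 core histone and 5 of 7 linker histone genes higher. Cell cycle genes with short transcripts had a median log2 ratio of 0.22 and those with long transcripts −0.07, and 16 of the 23 were higher. The short ones thus lacked the fall predicted for fewer dividing cells in that culture. However, the ratio is taken against replicates 1 and 2, and replicate 1 was itself low in these genes (4 of 23 higher, median −0.67). Their sums were 5687, 9350 and 6309 CPM in OPC replicates 1 to 3, so fewer dividing cells than in replicate 2 stay open. Loss of long transcripts in OPC replicate 3 may account for the CHD and INO80 genes. Genes of other kinds matched on length and level lay within 0.20 of that list (medians −0.48 and −0.68). Over all genes with 1 accession the slope of −0.27 per doubling of length fell short of the size predicted for such a loss. Slopes were 0.18 in OPC replicate 1, −0.11 in Astrocytes replicate 1 and 0.04 in DRG replicate 1. That of OPC replicate 1 partly mirrors it, as each slope is taken against the other replicates of the cell type. For the wider pattern, a loss in OPC replicate 3 cannot be told apart from a difference between cultures. Its 76 of 77 higher ribosomal protein genes (median 0.40) have short transcripts, with a median of 833 nucleotides over the 67 genes with 1 accession and a length, and the group of the shortest transcripts stood at 0.27, so the length trend goes with part of that rise. Its 14 of 14 higher microglia genes were not explained by these tests.

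Ribosomal protein genes were higher in OPC than in astrocytes and DRG neurons, although the list passed in neither comparison with an estimated correlation (adjusted p = 0.301 and 0.342). The tables argue against a trend with transcript length as the whole reason. Against astrocytes, 109 other genes matched on length and level had a median log2 fold change of 0.63. It differed by −1 from the 1.64 of the list. The matched genes themselves lay above the median of all genes (0.0852), so a trend with length or level may go with part of the rise. Scaling by library size, RLE or upper quartiles left the list's median at 1.51 or more. Reads without a unique alignment did not show the fall predicted if reads shared with pseudogenes were the reason. Their mean share was 8.70% in astrocytes and 9.43% in OPC, while the list's share of all reads rose by 2.63 percentage points, which together made 3.36 points. However, the share without a unique alignment was 11.8, 9.02 and 7.49% in OPC replicates 1 to 3 and covers all genes. With that spread it cannot decide about pseudogenes. A higher level of ribosomal protein mRNA in these OPC cultures may remain as a hypothesis, found and tested on the same data, and whether it belongs to the cell type, donor age or time in culture was not tested.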

How the results depend on the processing

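Chosen after the data had been seen were the tests on genes with 1 accession, on each accession alone, without a length trend, and without both Astrocytes replicate 1 and OPC replicate 3.

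Of 92 alternative counts of differing genes, 91 lay within 1.5 times the count given; the exception was DRG neurons against the mean of both glial types, 5881 genes when 3 and 6 libraries were fitted as plain groups, where the glial types differ within a group. Counts ran from 7075 to 9603 (DRG neurons and astrocytes), 6998 to 9467 (DRG neurons and OPC), 6346 to 8150 (OPC and astrocytes) and 5881 to 9744 (mean of both glial types). These ranges include fits on other sets of genes, such as the 11372 with the length trend removed, so they also reflect how many genes were tested. As single libraries were left out, the counts ran from 7758 to 9439, 7657 to 9451, 6492 to 8021 and 7637 to 9439 in the same order. With replicate number as a block they were 8747, 8694, 7421 and 8981, and 15, 18 and 20 lists passed between pairs of cell types, against 13, 17 and 19. Correlations of same-numbered libraries were −0.036 to 0.13, and 6 of 9 matched best with their own number, so pairing is left open. Enriched genes ran from 1625 to 2642 (DRG neurons), 918 to 1395 (OPC) and 1515 to 2269 (astrocytes). Thinned to 30710093 reads, the counts were 8669, 8612, 7414 and 8812, so depth changed them little.

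With a correlation estimated from the residuals, camera called 2 lists between DRG neurons and astrocytes (sensory neuron, synaptic vesicle), 0 between DRG neurons and OPC, and 1 between OPC and astrocytes (reactive astrocyte); at an unadjusted p under 0.05 it called 6, 6 and 5. No list that had passed changed direction under any scaling or other alternative.

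Among 250 results of named genes, 223 kept their direction and side of the threshold under every alternative run. Those that changed sign were never past the threshold, and the cause was not tested. H1f0 in DRG neurons against astrocytes went to 0.0271 with DESeq2, 0.0272 with RLE, 0.0344 with only the compared libraries, 0.0201 without the 2 libraries above, 0.13 without the length trend, and −0.179 to 0.0655 as single libraries were left out. H1f2 and H1f3 there went from −0.55 to 0.19 and from −0.77 to 0.42 as single libraries were left out. Chd2 in OPC against astrocytes went to −0.0209 with DESeq2, −0.0209 with RLE, −0.0450 with upper quartiles, −0.0213 with library size, −0.0388 with only the compared libraries, and −0.14 to 0.20 as single libraries were left out. Ino80 there went to −0.0102 with DESeq2, −0.0105 with RLE, −0.0282 with upper quartiles, −0.00976 with library size, −0.0241 with only the compared libraries, and −0.0823 to 0.22 as single libraries were left out. The list calls that ended were ependymal genes between DRG neurons and astrocytes (library size 0.0775, 1 accession 0.0678, length trend removed 0.0542) and those named in the comparisons. Scaling by RLE moved the median log2 fold change of all genes by 0.17 (DRG neurons and OPC) and 0.12 (mean of both glial types). Upper quartiles moved it by 0.14 (DRG neurons and OPC) and −0.11 (OPC and astrocytes), and library size by −0.26, −0.15 and −0.21 (DRG neurons against astrocytes, OPC and their mean).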

Other observations

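The isoforms described here were chosen after their values were seen, as was the description of OPC replicate 1.

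Isoforms of some genes went opposite ways between cell types. Of 1070 genes with at least 2 tested accessions, 78 had accessions called at least 2-fold higher and lower at once between DRG neurons and astrocytes, 63 between DRG neurons and OPC, and 30 between OPC and astrocytes. For Pkm, pyruvate kinase, accession NM_001253883 rose from 8.78 ± 2.48 CPM in astrocytes to 577 ± 274 in DRG neurons (log2 6.04, adjusted p = 1.13e-05), while NM_011099 fell from 129 ± 17.8 to 4.41 ± 1.57 CPM (log2 −4.87, adjusted p = 4.6e-06). For Gnao1, a G protein subunit, NM_010308 went from 96.9 ± 29.9 to 739 ± 50.5 CPM (log2 2.93, adjusted p = 1.55e-05) and NM_001113384 from 335 ± 94.2 to 10.8 ± 2.01 CPM (log2 −4.95, adjusted p = 1.81e-06). For Cdc42, a small GTPase, NM_001243769 went from 1.77 ± 0.198 to 131 ± 3.48 CPM (log2 6.21, adjusted p = 2.36e-07) and NM_009861 from 417 ± 19.6 to 190 ± 28.4 CPM (log2 −1.13, adjusted p = 0.000386). Kif1b, a kinesin motor, and Syngr1, a synaptic vesicle protein, had such pairs as well, with log2 fold changes of 6.04 and −3.63 and of 4.81 and −4.09. Each value rests on reads that fall in 1 accession alone.

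OPC replicate 1 differed from replicates 2 and 3 in genes of oligodendrocyte differentiation. Gpr17 stood at 786 CPM against 9.44 and 9.84, Neu4 at 65.1 against 2.79 and 6.16, Myrf, a regulator of myelin genes, at 63.8 against 5.41 and 6.14, Enpp6 at 7.60 against 0.0407 and 0, and Ugt8a at 135 against 75.3 and 39.8 CPM. Of 11 myelin genes tested, 8 were higher in it (median log2 ratio 1.14). Immediate early genes were higher in it for 0 of 14 genes (median −1.24), with Egr1 at 17.5 CPM against 198 and 162, and microglia genes for 0 of 14 (median −2.23). In OPC replicate 3, 13 of 14 immediate early genes were higher than the mean of replicates 1 and 2, which the low replicate 1 brings down. The list summed to 247, 560 and 594 CPM in OPC replicates 1 to 3.

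The libraries were also regrouped to see how many genes other groupings give. For each pair of cell types, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes as the real groups, and 10 splits are too few for a share under 0.05. The real counts were 8938, 8833 and 7689 (DRG neurons and astrocytes, DRG neurons and OPC, OPC and astrocytes), and the highest of the other splits was 0 with edgeR. For DRG neurons against the mean of both glial types, 1 of 100 drawn from 840 groupings, the real one with 9093 genes, gave as many. The highest other gave 5526. All other groupings put libraries of different cell types together, which raises the spread within groups and lowers the counts. The real groups were therefore bound to lead, and these splits cannot tell what chance alone would give.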
